A study of Homo sapiens with 4 samples.

How the data were processed

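RNA from U937 cells, an established human monocytic line, was measured by RNA sequencing in 4 libraries. The column names of all 4 libraries carry the term NoPMA, so none is labelled as treated with PMA. Per the labels, 2 libraries came from Cas9-expressing cells given a control guide RNA and 2 from cells given a guide RNA against DHX29. These groups are called Control and DHX29-KO. Per the labels' protocols, poly(A) RNA was isolated and libraries were made with a directional kit and sequenced on a NextSeq instrument. The labels number the replicates 1 and 2 in each group and do not say whether they were separate cultures, so p-values measure only the spread between these samples, which may be technical.

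The authors deposited raw read counts per gene, in 1 table with 1 column per library. Reads were processed with Trim Galore 0.6.10, HISAT2 2.2.1, and featureCounts of Subread 2.0.1, with the human build hg38, per the submitters' processing notes. The annotation release, the strand setting and the handling of reads with several matches are not given in the sources used here. The table holds 66023 gene records, of which 56927 matched an identifier of GENCODE release 29 on the primary assembly. The other 9096 included copies of genes on alternate sequences, and records outside the primary matches held between 7.28% and 7.33% of counts. Well-counted pairs of records with the same symbol, 1 on and 1 outside the primary assembly, were compared where their counts were already close. These 195 to 214 pairs per library differed by a median of 0.157 to 0.181 counting standard deviations. That is less than a random split of reads would give, so the same reads appear in more than 1 record for such pairs. Of 7369 pairs of tested records with overlapping gene spans, 485 had summed counts within 10 percent, 150 of these on opposite strands. Values of genes with near-identical copies or an overlapping partner are therefore uncertain.

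Library totals were 25382253 and 30784077 counts in Control 1 and 2 and 24011251 and 23628543 in DHX29-KO 1 and 2. A level of 3 counts corresponded to 0.0975 to 0.127 CPM, the count scaled to the library total. Replicates differed by more than counting noise, with a mean chi-square per gene of 2.69 between the Control libraries and 1.82 between the DHX29-KO libraries, where counting alone gives 1. They were kept as separate samples. The first axis of log2 CPM distances held 53.7% of the variance and separated the groups, and the second, with 24.4%, separated DHX29-KO 1 from DHX29-KO 2.

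The deposited counts were tested with edgeR 4.0.16 (quasi-likelihood test, TMM scaling, filterByExpr with a minimum count of 10) in R 4.3.3. All 4 libraries entered the fit, with group as the only term and 2 residual degrees of freedom. Benjamini-Hochberg adjustment covered the 19950 records tested, with a threshold of 0.05. Log2 fold changes are DHX29-KO over Control, and levels are CPM on TMM-scaled library totals, as mean ± SD with n = 2 libraries per group. Standard errors (SE) of edgeR log2 fold changes were back-calculated from the F statistic of the same test. They are therefore not a separate measure of the spread between libraries. Levels of the marker lists of other cell types, and of their members where a range over the 4 libraries is given, are CPM on library totals without that scaling. Gene lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the 32 lists with at least 5 tested members. Camera with an estimated correlation and fry were run beside it. Fry tests whether the genes of a list move on balance in 1 direction, or in either direction, and does not compare the list with other genes.

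The share of G and C at the third codon position (GC3), transcript length and untranslated region composition came from GENCODE release 29 sequences for 12240 tested protein-coding genes. Their relations to fold change were tested by 2-sided permutation of genes with 100000 draws, or 10000 in alternatives, in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Genes are not independent replicates, so differences between the libraries of a group served as the reference.

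Groups, main tests, gene lists, the alternatives marked as planned and the rule for naming genes were fixed before the data were examined. The rule named DHX29, the 12 protein-coding genes with the largest rise and the 12 with the largest fall among those past the threshold with a mean of at least 5 CPM and both DHX29-KO libraries beyond both Control libraries, up to 3 members with the smallest p of each list, and the tested neighbours of DHX29. Where a list had no member past the threshold, its member with the smallest p was named with values only. Any other gene named was chosen after its values were seen. Some genes that the rule names are not reported here. Lists written as symbol patterns were limited to protein-coding genes once the table was open and before any fit.

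The procedure was tested on simulated counts for the 19950 records, drawn from the real Control means and library sizes, with 200 genes changed. Dispersions followed the fitted trend with level, so records of equal level shared a dispersion. No trend with length or GC was simulated, so recovery in the real data may differ. For the comparison of DHX29-KO with Control, edgeR recovered 54% of genes changed 1.2-fold, 96% at 1.5-fold and 100% at 2-fold, and called 3 unchanged genes. DESeq2 recovered 36%, 82% and 98% and called 0 unchanged genes. In the same simulation, camera gave a planted list of 40 genes lowered 1.15-fold an adjusted p of 2.18e-17 with the preset correlation and 0.279 with an estimated correlation.

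Alternatives planned in advance were other scalings (RLE, upper quartile, library totals), no count filter, a minimum count of 50, DESeq2 1.42.0, limma-voom, a replicate block, leaving out each library in turn, a test against a 1.5-fold change, other list tests, and other gene sets and covariates for GC3. Primary assembly records alone, and a per-library correction for transcript length and GC with and without the replicate block, were added after the data were seen.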

Results

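Messenger RNA was counted in U937 cells, a human monocytic line, carrying Cas9 and either a control guide RNA or a guide RNA against DHX29, a DExH-box helicase that acts in translation initiation. Each group had 2 libraries, with totals from 23628543 to 30784077 counts. The comparison asked how loss of DHX29 changes gene expression in these cells.

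DHX29 itself (ENSG00000067248.9, chromosome 5, 55256245 to 55307722, minus strand, hg38) was measured at 31.4 and 30.7 CPM in Control 1 and 2 and at 10.9 and 10.1 CPM in DHX29-KO 1 and 2. The mean fell from 31.1 ± 0.501 to 10.5 ± 0.608 CPM (SD, n = 2 each), a log2 fold change of -1.56 (SE 0.0746, edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 1.09e-06). The labels and the targeted gene therefore point the same way in all 4 libraries. RNA level does not measure the protein. Of its 8 tested neighbours on 5q11.2, IL6ST, a cytokine receptor subunit, rose by the same test (log2 fold change 0.45, SE 0.11, adjusted p = 0.0176), and its call was lost with DESeq2 (adjusted p = 0.148), without Control replicate 2 (0.0646) and without DHX29-KO replicate 2 (0.0911). SKIV2L2, the adjacent gene, was not called (log2 fold change -0.07, SE 0.045), but was called lower with a correction for transcript length and GC (-0.13, adjusted p = 0.0113). PPAP2A, GZMA and MCIDAS were not called, and each passed the threshold in an alternative, PPAP2A on primary assembly records alone (adjusted p = 0.0432), MCIDAS with the length and GC correction (0.0361) and GZMA with that correction (0.0265), without a count filter (0.0293) and without Control replicate 1 (0.0258). CCNO, SLC38A9 and IL31RA were not called, and camera did not call the group (adjusted p = 0.684).

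**Figure D1:**
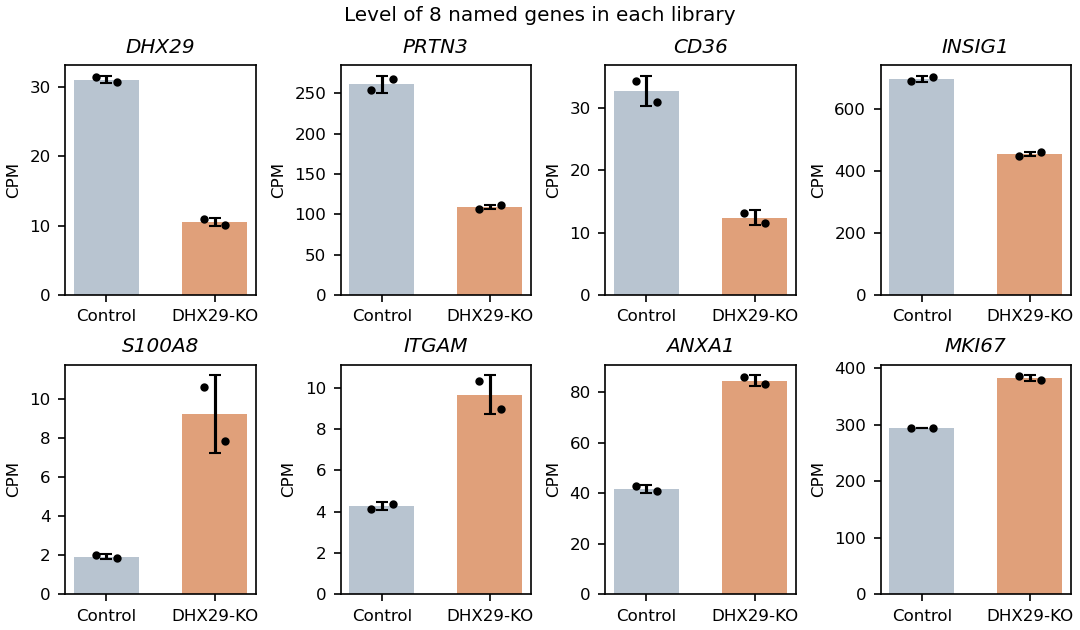
Level (CPM, scaled counts) of 8 named genes in Control and DHX29-KO libraries. Bars are means, error bars are SDs over n = 2 libraries and dots are single libraries; DHX29 averaged 31.1 CPM in Control and 10.5 CPM in DHX29-KO.

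Among the 12 protein-coding genes with the largest rises of those that the naming rule selects, S100A8, a subunit of calprotectin, increased from 1.93 ± 0.134 to 9.24 ± 1.98 CPM (n = 2 each, log2 fold change 2.27, SE 0.179, edgeR adjusted p = 3.10e-05), and its partner S100A9 from 21.8 ± 1.88 to 42.8 ± 1.51 CPM. ITGAM, the integrin subunit CD11b, rose from 4.25 ± 0.185 to 9.65 ± 0.944 CPM, and FPR2, a formyl peptide receptor, from 7.57 ± 0.67 to 14.8 ± 1.5 CPM. ANXA1, which encodes annexin A1, rose from 41.9 ± 1.55 to 84.7 ± 2.02 CPM (log2 fold change 1.02, SE 0.0437, edgeR adjusted p = 6.57e-07). TCHH, which encodes trichohyalin, rose from 1.98 ± 0.163 to 9.78 ± 0.529 CPM. The other 6 of the 12 were SYTL3, GCH1 (the initial enzyme of tetrahydrobiopterin synthesis), ANKRD22, CREBBP (a histone acetyltransferase), FAM208A and AOC1, with log2 fold changes from 0.92 to 1.07.

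Among the genes that fell, PRTN3, the neutrophil granule protease proteinase 3, dropped from 261 ± 10.2 to 109 ± 3.04 CPM (n = 2 each, log2 fold change -1.26, edgeR adjusted p = 4.35e-08). CD36, a scavenger receptor, fell from 32.7 ± 2.41 to 12.4 ± 1.18 CPM. IGLL1, a surrogate light chain gene, fell from 14.6 ± 0.637 to 4.5 ± 1.09 CPM (log2 fold change -1.70, SE 0.141), and the record AP000345.2 on the other strand overlaps it. MS4A7 fell from 14.5 to 6.03 CPM and HSPG2, which encodes the proteoglycan perlecan, from 14.5 to 6.12 CPM. The others of the 12 besides DHX29 were ABHD4, SMIM24, TPSAB1, C12orf75, ACTL8 and C6orf223, with log2 fold changes from -1.13 to -1.01. TPSAB1, a mast cell tryptase, has near-identical paralogs, so its value is uncertain.

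Over all 19950 records tested with edgeR, 2277 were higher and 2371 lower in DHX29-KO, against 7037 at an unadjusted p under 0.05. On the primary assembly, 2096 of 18049 were higher and 2208 lower. Most changes were small: the median absolute log2 fold change of called records was 0.263, and 69 primary assembly genes were higher and 99 lower by over 2-fold. DESeq2 called 1143 higher and 1163 lower records, and a test against a 1.5-fold change called 19 and 26. Library totals alone gave 2617 higher and 2120 lower, and upper-quartile scaling 1920 and 2697, so the balance of directions depended on the scaling.

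**Figure D2:**
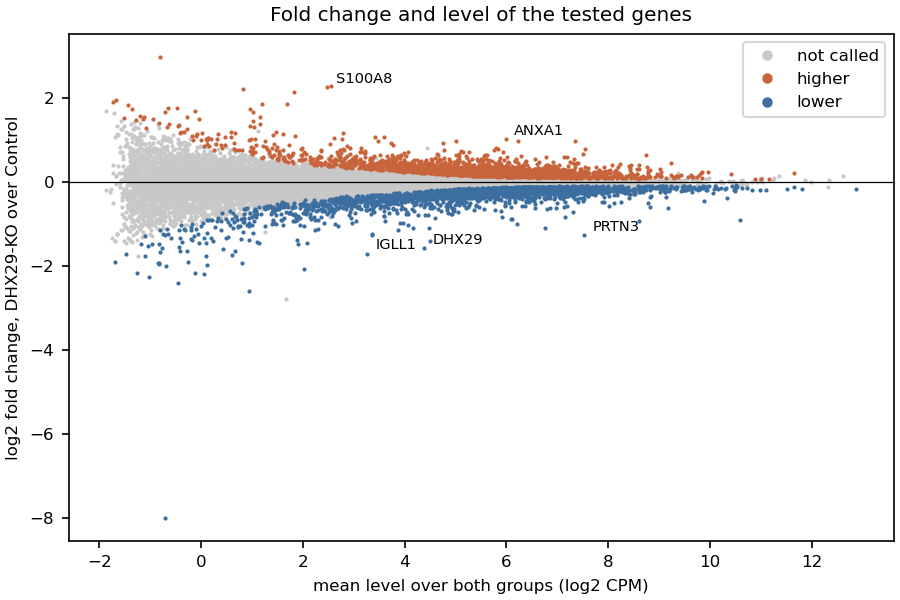
Log2 fold change (DHX29-KO over Control) against mean level (log2 CPM) for tested genes of the primary assembly; each dot is a gene, colored by its call at an adjusted p of 0.05. Of 18049 genes, 2096 were higher and 2208 lower.

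Monocyte and macrophage markers moved both ways. Of 28 measured members, 9 rose and 8 fell, or 10 and 8 adjusted over the list alone, and camera did not call the list (adjusted p = 0.427). LYZ, which encodes lysozyme, rose from 332 ± 9.5 to 523 ± 6.4 CPM and ITGB2, the integrin partner of ITGAM, from 508 ± 0.76 to 695 ± 14 CPM, while CD36 fell. Of 15 granulocyte progenitor and granule genes, 8 fell and 1 rose, or 9 and 1 adjusted over the list alone. The serine protease genes ELANE (neutrophil elastase) and AZU1 (azurocidin) fell with log2 fold changes of -0.92 and -0.72, and CEBPE, a granulocyte transcription factor, rose with 0.57. Camera called this list lower (adjusted p = 0.00904), with an adjusted p = 0.421 with an estimated correlation. The call was also lost with the length and GC correction and replicate block together (adjusted p = 0.0644, against 0.0459 without the block), although the median moved only from -0.254 to -0.197 with the correction, which called 8 members lower and 2 higher. PRTN3, ELANE and AZU1 each have a further record outside the primary assembly.

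Camera called the inflammatory and immediate early lists higher. Of 27 NF-kB and inflammatory response genes, 7 rose and 1 fell, or 10 and 1 adjusted over the list alone. Camera gave an adjusted p of 0.00215, and of 0.529 with an estimated correlation. Fry by direction did not call that list (adjusted p = 0.112). CCL2, a monocyte chemokine, and NFKB1, an NF-kB subunit, rose with log2 fold changes of 0.34 and 0.28, while the chemokine gene CCL5 fell from 50 ± 0.87 to 31.9 ± 0.28 CPM. Of 26 immediate early genes, 10 rose and 1 fell, the same counts as adjusted over the list alone (camera adjusted p = 0.0124, and adjusted p = 0.421 with an estimated correlation). FOSL2 and KLF4, both transcription factor genes, each had a log2 fold change of 0.78, and MYC, the gene that fell, had -0.56.

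Interferon-stimulated genes were divided, with 7 of 38 higher and 7 lower, also when adjusted over the list alone (camera adjusted p = 0.684). UBE2L6, a conjugating enzyme for ISG15, fell from 38.4 ± 0.73 to 22.7 ± 0.58 CPM, and MX2 and IFITM2 had log2 fold changes of -0.38 and -0.29. Of 17 genes of MHC class I presentation, 4 rose and 0 fell (4 and 1 adjusted over the list alone, camera adjusted p = 0.14), among them B2M (0.24), HLA-C (0.14) and ERAP1 (0.28). With the length and GC correction camera called that list higher (median 0.149, against 0.081 before, adjusted p = 0.0433, or 0.0476 with the replicate block). HLA-C is one of a family of near-identical genes and has several records, and ERAP1 was not called by DESeq2 (adjusted p = 0.118) or without DHX29-KO replicate 1 (0.108). Of 5 class II genes, CD74 alone was called (-0.31), a call lost in several alternatives including DESeq2 (adjusted p = 0.212), against 1 higher and 1 lower adjusted over the list alone. The median of that list was -0.095, its mean 0.227 and its camera adjusted p 0.824.

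Camera called the cholesterol and ATF4 target lists lower. Of 23 cholesterol biosynthesis genes, 20 fell and 0 rose, or 21 and 1 adjusted over the list alone, with a median log2 fold change of -0.375 (camera adjusted p = 1.76e-09, and adjusted p = 0.421 with an estimated correlation). INSIG1, a sterol sensor of the endoplasmic reticulum, fell from 697 ± 8.6 to 455 ± 7.8 CPM, FDFT1 (squalene synthase) fell from 518 ± 3.3 to 369 ± 12 CPM, and HMGCS1 (HMG-CoA synthase) had a log2 fold change of -0.61. Of 37 ATF4 and integrated stress response targets, 26 fell and 1 rose, or 29 and 1 adjusted over the list alone, with a median of -0.189 (camera adjusted p = 3.45e-08, and adjusted p = 0.421 with an estimated correlation). PCK2, a mitochondrial gluconeogenic enzyme, had a log2 fold change of -0.60, WARS, a tryptophanyl-tRNA synthetase, -0.38, and CBS, which makes cystathionine, -0.71. CBS has a near-identical copy on the same chromosome. PPP1R15A, the GADD34 phosphatase subunit, was the gene that rose (0.33).

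Other stress and metabolic lists were not called by camera. Of 22 unfolded protein response chaperones, 3 rose and 4 fell (3 and 5 adjusted over the list alone, camera adjusted p = 0.98), with PDIA6 at -0.20, SEC61B at -0.30 and ERO1L at 0.26. Of 17 heat shock proteins, 7 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.242), with HSPB1 at -0.30, HSPA1A at 0.30 and DNAJA1 at 0.18; HSPA1A has a near-identical paralog. Of 16 NRF2 targets, 3 rose and 4 fell, also adjusted over the list alone (camera adjusted p = 0.53), with TALDO1 at -0.23. SLC7A11 (-0.28) and SRXN1 (-0.25) in that list were not called by DESeq2 (adjusted p = 0.0523 and 0.0719). Of 24 glycolysis genes, 4 rose and 3 fell (5 and 4 adjusted over the list alone, camera adjusted p = 0.794), LDHA with 0.17 and LDHB with -0.25. Of 15 hypoxia-inducible genes, ERO1L rose and 3 fell (2 and 3 adjusted over the list alone, camera adjusted p = 0.738), among them PDK1 (-0.28) and DDIT4 (-0.38). Of 26 autophagy and lysosome genes, 3 rose and 5 fell (3 and 6 adjusted over the list alone, camera adjusted p = 0.59), including the lysosomal protease CTSD (-0.37). NEU1 (-0.36) has records on alternate sequences whose fold changes differ in sign, so its value is uncertain.

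Camera called both cell cycle lists higher. Of 45 G2/M and mitosis genes, 31 rose and 1 fell (CKS2), or 34 and 2 adjusted over the list alone, with a median log2 fold change of 0.154 (camera adjusted p = 1.08e-08, and adjusted p = 0.421 with an estimated correlation). MKI67, the Ki-67 proliferation antigen, increased from 294 ± 0.44 to 382 ± 5.1 CPM, SMC4, a condensin subunit, from 302 ± 7.1 to 384 ± 6.9 CPM, and CENPF, a kinetochore protein, from 237 ± 0.74 to 289 ± 2.1 CPM. Of 41 G1/S and DNA replication genes, 16 rose and 0 fell, or 20 and 1 adjusted over the list alone (median 0.099, camera adjusted p = 5.31e-05, and adjusted p = 0.421 with an estimated correlation). RRM2, a ribonucleotide reductase subunit, had a log2 fold change of 0.42, CCNE2 (cyclin E2) 0.71 and UHRF1 0.36. Of 33 replication-dependent histone genes, 10 fell and 0 rose, also adjusted over the list alone, among them HIST1H1C (-0.33), HIST2H2AA3 (-0.52) and HIST1H2BK (-0.46). Camera called that list lower (adjusted p = 0.00953, and adjusted p = 0.684 with an estimated correlation), and the call was lost without Control replicate 1 (0.0568) and without DHX29-KO replicate 2 (0.0681). The length and GC correction also ended it, with a median of -0.13 against -0.22 before (adjusted p = 0.15, or 0.20 with the replicate block). Fry by direction did not call the histone list (adjusted p = 0.101). Histone transcripts mostly lack poly(A) tails, and HIST2H2AA3 has a near-identical copy.

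Of 23 p53 targets, 7 rose and 2 fell (9 and 2 adjusted over the list alone, camera adjusted p = 0.0572), RRM2B with 0.39, TNFRSF10B with 0.26 and CCNG1 with -0.20; camera called the list without DHX29-KO replicate 1 (adjusted p = 0.0346) and with the length and GC correction (0.0482, median 0.123 against 0.109 before), but not with that correction and the replicate block (0.0689). Of 15 BCL2 family genes, 4 rose and 3 fell, also adjusted over the list alone (camera adjusted p = 0.959). Among them the survival gene BCL2A1 fell from 27.4 ± 0.74 to 18.0 ± 0.046 CPM, MCL1 rose (0.30) and BIK fell (-0.65).

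Camera called 3 lists of the translation apparatus lower. Of 78 cytosolic ribosomal protein genes, 60 fell and 0 rose, or 69 and 0 adjusted over the list alone, with a median log2 fold change of -0.122 (camera adjusted p = 4.43e-10, and adjusted p = 0.421 with an estimated correlation). RPL5 fell from 866 ± 7 to 735 ± 22 CPM, and RPL3 and RPL4 each had a log2 fold change of -0.19. A correction for transcript length and GC ended the list's call, with a median of -0.026 and a camera adjusted p of 0.109. With that correction 26 of 77 members with a value were called lower and 8 higher. Of 77 mitochondrial ribosomal protein genes, 33 fell and 0 rose, or 40 and 0 adjusted over the list alone (median -0.145, camera adjusted p = 1.76e-09, and adjusted p = 0.421 with an estimated correlation), with MRPS6 at -0.40, MRPS5 at -0.29 and MRPS22 at -0.35. With the length and GC correction the median was -0.074 and the list stayed called (adjusted p = 0.000199). MRPS6 shares its span with SLC5A3, so its value is uncertain. Of 46 translation initiation factors, 16 fell and 5 rose, or 18 and 5 adjusted over the list alone (camera adjusted p = 0.0247, and adjusted p = 0.687 with an estimated correlation). EIF4EBP1, a translation repressor, fell from 178 ± 4.7 to 139 ± 0.23 CPM, and the eIF3 subunits EIF3E and EIF3L had log2 fold changes of -0.32 and -0.28. The 5 that rose were EIF4G1, EIF4G2, EIF4A1, EIF3A and EIF4G3. The call was lost without Control replicate 1 and without DHX29-KO replicate 1. Fry by direction did not call the list of initiation factors (adjusted p = 0.0933). With the length and GC correction camera still called it lower (median -0.06, adjusted p = 0.00864, or 0.0128 with the replicate block).

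Of 40 ribosome biogenesis genes, 4 rose and 7 fell, or 4 and 9 adjusted over the list alone (camera adjusted p = 0.684), with MYC at -0.56, NPM1 at -0.20 and NOP2 at 0.22. Of 48 mRNA decay and codon-linked repression factors, 14 rose and 0 fell, or 16 and 3 adjusted over the list alone (median 0.052, camera adjusted p = 0.0121, and adjusted p = 0.592 with an estimated correlation). GIGYF1, a translation repression factor, had a log2 fold change of 0.25, the helicase of nonsense-mediated decay UPF1 0.21 and the decapping enzyme DCP2 0.29. That call was lost without Control replicate 2 and with the length and GC correction (camera adjusted p = 0.158, median 0.036). Fry by direction did not call the list of decay factors (adjusted p = 0.0933). Of 21 other DExH-box helicases, DHX38 (0.27), DHX15 (0.13), SNRNP200 (0.10) and DHX9 (0.10) rose and 0 fell. The counts adjusted over the list alone were the same, and camera did not call the list (adjusted p = 0.143). With the length and GC correction 2 were higher and 3 lower, with a median of 0.03 against 0.073 before. SNRNP200 was not called without Control replicate 2 (adjusted p = 0.118) or without DHX29-KO replicate 2 (0.141). Of 355 C2H2 zinc finger genes, 34 rose and 19 fell, or 25 and 14 adjusted over the list alone (camera adjusted p = 0.449), with ZNF609 at 0.33, ZNF318 at 0.27 and ZNF438 at -0.35.

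Camera called the nuclear genes of oxidative phosphorylation lower. Of 77, 38 fell and 0 rose, or 48 and 0 adjusted over the list alone, with a median log2 fold change of -0.126 (camera adjusted p = 1.76e-09, and adjusted p = 0.421 with an estimated correlation). The complex I subunits NDUFB9, NDUFS5 and NDUFA8 fell, from 320 to 260, from 201 to 167 and from 53.4 to 41.5 CPM. With the length and GC correction the median was -0.044 and the list stayed called (adjusted p = 0.00757). Of 13 mRNAs encoded by the mitochondrial genome, MT-CYB (0.24) and MT-ATP6 (0.21) rose and 0 fell, also adjusted over the list alone (camera adjusted p = 0.143). Neither gene was called by DESeq2 (adjusted p = 0.0822 and 0.107), and without Control replicate 2 camera called the list (0.000781). With the length and GC correction 6 members of that list had a value and all 6 were called higher. Their median was 0.207, against 0.127 before, and camera did not call the list (adjusted p = 0.0729). The share of counts from the mitochondrial genome was 3.15% and 3.70% in the Control and 3.72% and 3.53% in the DHX29-KO libraries.

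**Figure D3:**
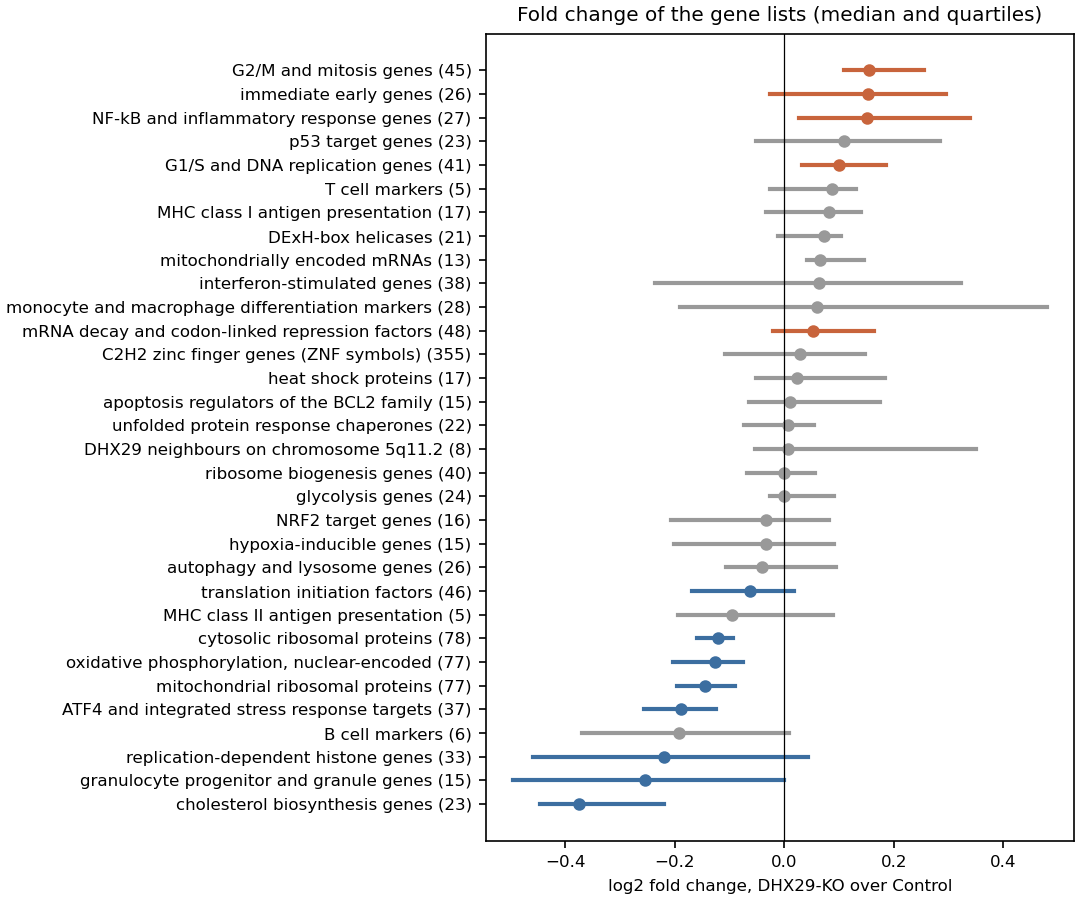
Median log2 fold change (dot) and quartiles (line) of the members of each gene list with at least 5 tested genes, with the number tested in brackets; orange lists were called higher, blue lists lower and gray lists not called by camera at an adjusted p of 0.05. Cholesterol biosynthesis genes had the lowest median, -0.375, and 13 of 32 lists were called.

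In CPM on library totals without TMM scaling, the median level of T cell, epithelial, erythroid and fibroblast marker lists was at or close to 0 CPM in every library, and that of B cell markers was 1.95 and 1.74 CPM in Control and 2.08 and 2.14 CPM in DHX29-KO. On that scale single members were higher: 2 of 15 T cell, 1 of 10 B cell and 2 of 16 erythroid and megakaryocyte markers had a mean over 5 CPM, among them CD4 (59.8 to 65.9 CPM over the 4 libraries), LAT (14.3 to 17.6) and TFRC (279 to 325). Of 5 tested T cell markers CD4, which monocytes also express, had a log2 fold change of -0.13 (0 higher and 1 lower, also adjusted over the list alone, camera adjusted p = 0.794). Of 6 B cell markers EBF1 had 0.82 and PAX5 -0.33 (1 and 1, or 1 and 2 adjusted over the list alone, camera adjusted p = 0.329). All 3 genes lost their edgeR call when a library was left out, EBF1 without DHX29-KO replicate 1 (adjusted p = 0.195), CD4 without each of the 4 libraries in turn (0.0751 to 0.178) and PAX5 without Control replicate 2 (0.186) or either DHX29-KO library (0.0912 and 0.137). Of 3 erythroid and megakaryocyte markers TFRC, the transferrin receptor of dividing cells, rose (0.16, or 1 higher and 1 lower adjusted over the list alone). The epithelial marker tested, CLDN4, was at 0.599 and 0.438 CPM with TMM scaling and not called. None of 3 fibroblast markers was called (0 over all genes and adjusted over the list alone), and COL1A1 was at 0.575 and 0.918 CPM on the same scale.

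Fold change was related to the composition of transcripts. Genes that rose had a median GC3 of 53.2% (1889 genes) and those that fell 64.7% (1811 genes), against 60.0% over the 12240 protein-coding genes tested. The difference of -11.5 percentage points had a permutation p of 1e-05, the smallest that the draws can give. Across genes, which are not independent replicates, Spearman's rho between GC3 and log2 fold change was -0.144 (permutation p = 1e-05, again the smallest possible). The same correlation was 0.054 for Control 2 over Control 1 and -0.179 for DHX29-KO 2 over DHX29-KO 1. Each of the 4 pairs of a DHX29-KO and a Control library gave a negative rho, from -0.192 to -0.075. Median log2 ratios ran from 0.0663 in the lowest to -0.0365 in the highest GC3 decile for the fold change, and from 0.0321 to -0.027 between the DHX29-KO replicates, so the replicates differed more by rho and less by decile medians. Without DHX29-KO replicate 2 rho was -0.0955, and given the GC of the 3′ untranslated region and transcript length it was -0.015 (permutation p = 0.0374).

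Transcript length gave the stronger relation, examined after the results were seen. The median annotated transcript was 4191 nt long for genes that rose and 2097 nt for genes that fell, against 2929 nt overall. Spearman's rho with log2 fold change was 0.282 across genes (permutation p = 1e-05, the smallest possible), and -0.039 and 0.037 between the replicates of Control and of DHX29-KO. Each of the 4 pairs of a DHX29-KO and a Control library gave a rho between 0.241 and 0.283. With a per-library correction for transcript length and GC, camera still called the G2/M and ATF4 target lists (adjusted p = 1.19e-07 each). It also called the G1/S (7.19e-05), NF-kB (0.0015) and immediate early (0.0133) lists, while 3 other lists lost their call. That correction moved the log2 fold change of several named genes by over 1.5 times. Values came closer to 0 for IFITM2 (-0.15), RPL5 (-0.16), RPL3 (-0.11), EIF4EBP1 (-0.23), SEC61B (-0.18), HSPB1 (-0.17), HIST1H1C (-0.19), HIST1H2BK (-0.28), NDUFB9 (-0.18), NDUFS5 (-0.15), TALDO1 (-0.14), CENPF (0.17), DCP2 (0.17) and TFRC (0.096), which stayed called. SNRNP200 (0.047) and CD74 (-0.19) lost their call, and HLA-C moved further from 0 (0.23). CD74 also lost it without DHX29-KO replicate 1 (-0.21, adjusted p = 0.26). MT-ATP6 was at 0.13 without Control replicate 1 and at 0.32 with the correction and replicate block.

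**Figure D4:**
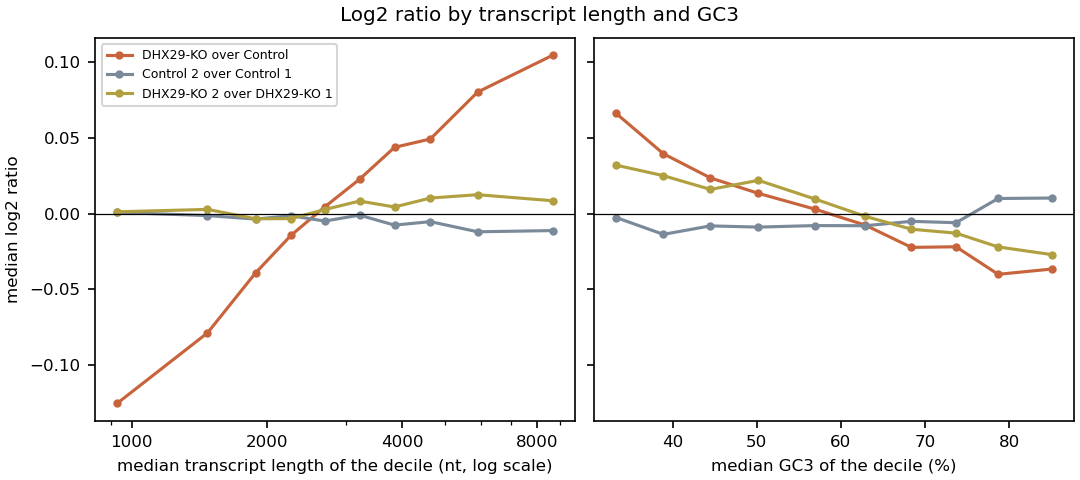
Median log2 ratio of 1224 genes per decile against the median transcript length of the decile (nt, log scale) or its median GC3 (%), for DHX29-KO over Control and for replicate 2 over replicate 1 of each group. The fold change runs from -0.125 in the shortest to 0.105 in the longest decile, while the replicate ratios of DHX29-KO follow GC3 in the same direction as the fold change, over a smaller range.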

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

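The primary assembly and length and GC corrections were chosen only after the results were seen; the other alternatives were planned. DHX29 stayed lower in every alternative, with log2 fold changes from -1.63 to -1.50. Counts of higher and lower records moved by over 1.5 times with DESeq2, to 1143 and 1163, of which 1142 and 1163 were among the edgeR calls, and with a test against a 1.5-fold change, to 19 and 26. The test against 1.5-fold asks for larger changes by construction. DESeq2 was given 33745 records under its own filter, against 19950, and in simulated counts it recovered 36% of 1.2-fold changes where edgeR recovered 54%; the part of each in the lower counts was not separated. With the replicate block 2218 were higher and 2325 lower. Same-numbered libraries deviated from their group means with a correlation of 0.006, which shows no pairing by number. Low-count records weigh equally in that correlation, so a shared effect could be missed. Leaving out 1 library, with the lone sample assumed to vary like the other group, gave 1807 to 2109 higher and 1868 to 2076 lower records. No record was called in opposite directions in any alternative. Camera called 13 of 32 lists, and 0 with an estimated correlation, where 2 had an unadjusted p under 0.05; fry called 9 by direction and 31 in either direction. With 2 libraries per group, camera with an estimated correlation gave an adjusted p of 0.279 for a list lowered in simulated counts. That test thus missed a change planted there. Genes were simulated independently, so this does not show whether the preset correlation calls too many lists of genes that vary together. Of 107 named genes past the threshold besides DHX29, 96 kept their call in every alternative that gave them a value. The test against a 1.5-fold change was not applied to single named genes. Most named genes were chosen for small p or for separated libraries, which favours that outcome. GC3 and fold change had rho from -0.185 to -0.0955 with 1 library left out.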

Other observations

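In this part, the tests of drift between libraries, of RNA handling, of reads counted in several copies and of a maturation shift were chosen only after the results were seen; the matched-list tests were written down after the length and GC correction had been seen but before their own results.

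A pair of neighbouring genes on chromosome 7, chosen after their values were seen, rose from low levels. GPR141, a G protein-coupled receptor gene (37683796 to 37833788), was at 0.515 and 0.72 CPM in Control and 3.07 and 2.78 CPM in DHX29-KO (log2 fold change 2.22, SE 0.239, edgeR adjusted p = 0.000183). NME8 (37848597 to 37900401) was at 0.0793 and 0.164 CPM in Control and 1.04 and 1.01 CPM in DHX29-KO (log2 fold change 2.98, SE 0.454, edgeR adjusted p = 0.00121). Its level in Control 1 lay under the level of 3 counts in that library (0.118 CPM), so the size of its fold change is uncertain. EPDR1, whose span overlaps both, was at 73.7 and 72.8 CPM and was not called (log2 fold change -0.02).

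Fold change rose with transcript length, with 31.8% of the shortest decile called lower and 31.4% of the longest called higher, and the lower level of ribosomal protein and respiratory chain mRNAs may be part of that trend. Drift between libraries of a group is argued against by correlations with length no stronger than -0.039. A difference in RNA handling between the groups cannot be told apart from an effect of DHX29. Each pair of a DHX29-KO and a Control library showed the trend (weakest rho 0.241), and the labels give no preparation batch. The cytosolic ribosomal protein list had a median of -0.122. That lay within the middle 95% (-0.149 to -0.032) of 10000 lists of other genes matched on length and GC. The correction brought the median to -0.026 and ended the list's call, so the trend could account for the fall of the median. With the correction 26 members were still called lower and 8 higher. For nuclear respiratory chain genes the tests part: the median of -0.126 lay within the matched range (-0.141 to -0.015), which by the criterion written beforehand favours the trend, but the correction left a median of -0.044 that camera still called (adjusted p = 0.00757; 0.00977 with the replicate block). This explanation was therefore left undecided for that list, a reading adopted after both results were seen; cholesterol genes, at -0.375 before and -0.332 after the correction, stayed called (adjusted p = 5.27e-09).

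The higher GC3 of genes that fell may come from drift in GC bias between libraries. The 2 DHX29-KO libraries differed along GC3 with a rho of -0.179, larger in size than the -0.144 of the fold change. Drift was not shown to be the whole source. All 4 single differences of a DHX29-KO and a Control library had a negative rho (-0.192 to -0.075), and the Control libraries differed by 0.054. Decile medians spanned more for the fold change (0.0663 to -0.0365) than for the DHX29-KO replicates (0.0321 to -0.027). The single differences share libraries, so their common sign does not decide against drift. The partial correlation of GC3 was smaller in size than that of the GC of the 3′ untranslated region, by -0.0451 (bootstrap SE 0.0167). The DHX29-KO replicates differed along both measures, with a rho of -0.179 for GC3 and -0.169 for the GC of that region. Drift could therefore shape both partial correlations, so their comparison does not decide on an effect of codon position in particular. The GC of the 5′ untranslated region had a rho of 0.005 with the fold change over 11811 genes. In the 4 single differences that rho was from -0.009 to 0.013. An effect of DHX29 on GC-rich transcripts stays open and was not tested apart from the drift in GC bias.

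Granule protease genes fell while S100A8, S100A9, ITGAM and LYZ rose. Reads counted in several copies are argued against for the 4 that rose, since 4 of 4 have a single record and were called. These 4 were chosen among called genes, so only the single records bear on this. Of the proteases only 1 of 4, CTSG, has a single record, so that explanation cannot be told apart there by this test. All 8 genes, CTSG included, kept their call in each of the 4 fits without 1 library, but genes chosen for small p or for separated libraries favour that outcome, so whether 1 library decides the calls was not settled. The listed monocyte and macrophage markers did not all move in 1 direction. Of the 17 called, 9 rose and 8 fell, CD36 with a log2 fold change of -1.40 (SE 0.086). The share that rose, 52.9%, was known before the bound for it was set. That test therefore does not decide on a uniform shift toward monocyte and macrophage maturation. A shift of only some of the markers was not settled. An effect of targeting DHX29 and a difference between the cell populations that received each guide both stay open and were not tested.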
